A study of Homo sapiens with 26 samples.

How the data were processed

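The series measured 9 human breast cancer cell lines that all descend from MCF-7, an estrogen receptor-positive line. They form 2 models of resistance to tamoxifen, a drug that binds the estrogen receptor and blocks its action in breast cells. In the TAMR model the parent line is MCF-7/S0.5, and TAMR1, TAMR4, TAMR7 and TAMR8 grew from separate colonies that emerged under 1 µM tamoxifen. These 4 lines were kept in medium with 1% fetal calf serum and 1 µM tamoxifen, and the labels do not clearly state the parent's medium. In the LCC model LCC0 depends on estrogen and responds to tamoxifen. LCC1 was derived from it without estrogen, through passage in ovariectomized nude mice, and still responds to tamoxifen. LCC2 was selected from LCC1 with tamoxifen, and LCC9 was selected from LCC1 with fulvestrant, an estrogen receptor degrader, and is cross-resistant to tamoxifen. The LCC lines were kept in medium without phenol red, with 5% charcoal-stripped serum. The 26 samples are 9 RNA-seq libraries, 9 small RNA libraries, and 4 libraries each of reduced representation bisulfite sequencing (RRBS, which reads CpG-rich DNA) and of digital gene expression (DGE, which counts short tags near the 3' end of transcripts) from the LCC lines. Each line has 1 library per assay.

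The authors aligned the RNA-seq reads with TopHat and quantified them with Cufflinks, mapped the RRBS reads with Bismark and the DGE tags with BWA, all on build hg19, and the labels state no versions and no tool for the small RNA reads. The RNA-seq tables hold FPKM per gene as deposited by the authors, with the layout of pairwise tests between lines. Their q-value columns hold an adjusted p-value for each pair of lines, per the file headers, from tests of 1 library against 1. The deposited small RNA table holds an expected count per mature miRNA, of which 90.1% are whole numbers, and the rest were rounded before any count model. The deposited DGE table holds a signal per gene, tag counts that the authors scaled to a common total of 2243882 per library. Dividing by each library's smallest value recovered whole reads for 100.0% of the values within 0.001. The RRBS table holds the percent of methylated reads per cytosine position, as deposited by the authors, with no coverage and no statement of whether positions count from 0, so windows of 1000 bp could be shifted by a single base.

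The RNA-seq tables listed 25134 genes for the LCC lines and 25153 for the TAMR model. Genes marked as failed in any pair were left out (19 and 17), and of the 512 and 528 symbols with several entries the entry with the highest mean was kept, which left 23659 and 23660 genes. The identifiers beginning with XLOC stand for loci without a symbol and are numbered separately in each table, so they were never compared between models. Gene names were used as the files give them. DGE listed 19070 genes, of which 17975 were also in the LCC RNA-seq table.

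The depth of the RNA-seq and RRBS libraries is not in the files and is unknown here. The small RNA libraries held between 6419894 reads in TAMR7 and 9157063 in LCC0. At 10 CPM (reads of a miRNA scaled to a common library total) the smallest of them has 64 reads and a 95% Wilson interval of 7.81 to 12.7 CPM, and a count of 0 allows up to 0.467 CPM (3 reads). The DGE libraries held 1337910 reads in LCC0, 1583224 in LCC1, 3096827 in LCC2 and 2957566 in LCC9. A DGE count of 0 allows up to 5.03 scaled tags in LCC0, 4.25 in LCC1, 2.17 in LCC2 and 2.28 in LCC9. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

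Groups follow the labels. With 1 library per line, the p-value of a single gene or miRNA measures the spread between lines, and in the TAMR model the parent's single library is assumed to vary like the TAMR lines. The tests also treat the 4 TAMR lines as independent. TAMR4 and TAMR7 were nearly alike (411 genes at least 2-fold apart, against 1052 or more in every other pair). Standard errors and p-values of comparisons with the TAMR lines may therefore be too small. P-values of gene lists with a preset correlation, described below, compare a list with other genes. Fisher's exact p-values compare counts of genes. Neither measures the spread between lines. RNA-seq and DGE values were tested with limma 3.58.1 (trend) on log2 of the value plus 1, for genes with a mean of at least 1. Small RNA counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr), in R 4.3.3. The comparison over both models had model as a term. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The design named edgeR for DGE only if the table held counts. As the table was scaled, limma was used, and edgeR on the recovered reads was added after the data were seen. Pairs of single LCC lines had no test. A gene was counted when it differed at least 2-fold on log2 of the value plus 1 in the same direction in RNA-seq and DGE, with a level of at least 1 in either line of the pair. A miRNA was counted when it differed at least 2-fold with at least 10 CPM in either line and 1 CPM added.

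Without coverage the planned Fisher test per CpG was not possible. The 2 strands of a CpG, whose methylation is usually equal, served as an internal check. A pair joined a cytosine listed on the minus strand with one listed on the plus strand at the next position. With strands named by the reference sequence, that order is G then C rather than C then G. The pairs were taken as CpGs and not checked against the sequence, so all values called CpG methylation below carry this limit. Of 1359724 CpG pairs on chromosomes 1 to 22 and X, the 1196043 (88.0%) with a mean gap between strands of at most 25 points over the 4 lines were kept. By its construction that filter raised the correlation between strands, in LCC0 from 0.821 to 0.983. A CpG was counted as different when both strands differed by at least 25 points in the same direction. Means were taken over windows of 1000 bp and over the CpGs within 1000 bp of the locus end richer in CpGs, each with at least 5 CpG pairs. The files give no strand of genes, so that end may not be the promoter.

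Before the data were examined, 19 gene lists and 11 miRNA lists, the comparisons, the alternatives and the rule for named genes were fixed. The gene lists cover estrogen receptor targets, the estrogen receptor and its cofactors, growth factor receptors and ligands, cell cycle, cyclin-dependent kinase inhibitors and p53 targets, apoptosis, luminal markers, basal markers, epithelial-mesenchymal transition, interferon response, cholesterol synthesis, unfolded protein response, drug transport and tamoxifen metabolism, hypoxia and glycolysis, NF-kappaB and cytokines, HOX and stem cell genes, DNA methylation and cancer-testis genes, markers of other cell types, and mitochondrial, ribosomal and histone transcripts. The miRNA lists cover the miR-200, miR-221/222 and let-7 families, the miR-17-92 clusters, the miR-99a/miR-100/miR-125b clusters, HOX cluster miRNAs, estrogen-linked miRNAs, the miR-15/16 and miR-34 families, the 14q32 cluster, the 19q13 cluster and miRNAs of other cell types. In the TAMR comparison each list was tested with camera of limma with its preset correlation and with an estimated one. In the single LCC pairs a list's median was ranked among 10000 random lists matched on expression, as a description. Named genes are the 10 highest and 10 lowest by the smallest change over the 4 TAMR lines after those past the threshold, the 8 highest and 8 lowest by the smaller of the RNA-seq and DGE changes in the LCC comparisons, 6 and 6 miRNAs and methylation windows, all genes shared between models up to a limit, ESR1, PGR, TFF1, GREB1, EGFR, ERBB2, FGFR1, BCL2 and CCND1 always, and 2 to 4 members of each list. The text names most of these and summarises the rest.

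The group tests, the ranking of lists, the strand rule and the count of gene blocks were tested on simulated data, and the camera tests, the counts in LCC pairs, the overlap between models and the correlation of methylation with expression were not. In the TAMR RNA-seq comparison the test recovered 2.99% of genes changed by log2 1, 53.7% by log2 2 and 97.0% by log2 4, with 7 false calls. In the LCC RNA-seq comparison these were 4.48%, 80.6% and 90.9% with 24 false calls, and in DGE 0%, 10.4% and 65.2% with 7. For miRNAs they were 8.96%, 22.4% and 77.3% with 1 false call in the TAMR model, 2.99%, 49.3% and 84.8% with 4 in the LCC model, and 17.9%, 76.1% and 92.4% with 7 over both. Of 100 simulated lists of the 12240 genes, 2 passed the 97.5th percentile with nothing added, 89 with log2 0.5 added and 100 with log2 1 added. The simulated genes varied independently of one another. Genes of a real list can vary together and then reach extreme percentiles more often, so these rates need not hold for the real lists. The strand rule recovered 91.8% of 1000 CpGs changed by 40 points at 30 reads per strand, with 1 false call among 29902 pairs. That depth was a chosen setting. The coverage of the real libraries is unknown, so neither rate can be carried over to them. The count of gene blocks gave 49 blocks over 9127 simulated genes with nothing added, and 100 blocks with log2 0.8 added to a run of 100 genes, of which 87 lay in that run. Other tools were DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered pseudocounts, filters, scaling, tools, fold limits and leaving out each line. Alternatives by CpG coverage and by the most abundant transcript were not run, because the files give neither.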

Results

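PGR, GREB1 and NPY1R, which estrogen induces, were lower in all 4 tamoxifen-resistant TAMR lines than in their parent MCF-7/S0.5, though none of them passed the threshold with all lines included. The 4 TAMR lines were kept in 1 µM tamoxifen, while the parent's medium is not clearly stated. In every comparison with this parent, exposure to the drug and resistance to it therefore cannot be told apart. PGR, the progesterone receptor, is a classical target of the estrogen receptor and had 38.2 FPKM in the parent (mean log2 change −4.86, standard error 0.62, limma adjusted p = 0.125). It was at 0.0165 in TAMR1, 0.128 in TAMR7 and 1.87 in TAMR8, and listed at 0 in TAMR4. GREB1, an estrogen-induced cofactor of the receptor, was at 133 FPKM in the parent and 0.199, 0.640, 1.30 and 16.7 in TAMR1, TAMR4, TAMR7 and TAMR8 (log2 −5.49, standard error 1.32, limma adjusted p = 0.386). NPY1R, a neuropeptide Y receptor induced by estrogen, was at 299 FPKM and between 1.32 and 16.6 (log2 −5.72, standard error 1.00, limma adjusted p = 0.224). ESR1, the estrogen receptor itself, was at 74.7 FPKM in the parent and 52.9, 31.9, 57.1 and 104 in the 4 lines. TFF1, a secreted trefoil peptide under estrogen control, lay on both sides of its 2109 FPKM in the parent (403, 4047, 892 and 4781, log2 −0.38, and 0.29 without TAMR1).

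Other transcripts were low in all 4 lines as well. IL20, a cytokine of the interleukin-10 family, was at 26.8 FPKM in the parent and at most 1.30 in a resistant line (log2 −4.36, limma adjusted p = 0.104). BMPER, which binds bone morphogenetic proteins, was at 11.8 and at most 0.0745 (−3.66, adjusted p = 0.0628), and PDLIM3, an actin-associated protein, at 11.9 and at most 0.226 (−3.50, adjusted p = 0.0698). ELOVL2, an enzyme that elongates polyunsaturated fatty acids, was at 33.2 FPKM in the parent and at most 2.30 (−4.60, adjusted p = 0.141). PLXDC2, a membrane protein, was at 15.6 and at most 0.618 (−3.62, adjusted p = 0.0964). It and the unnamed loci XLOC_003331 and XLOC_002484 (16.4 FPKM in the parent, at most 0.710) lie next to each other on chromosome 10 between positions 19494110 and 20571831. Of the genes higher in every line, SOX2, a transcription factor of stem cells, was at 0.173 FPKM in the parent and 7.06, 6.75, 10.5 and 16.2 in the 4 lines (log2 3.17, standard error 0.48, limma adjusted p = 0.149). GPX3, a secreted glutathione peroxidase, was at 1.79 and 12.2, 19.4, 24.1 and 21.5 (log2 2.82, standard error 0.40, adjusted p = 0.141). ATP2A3, a calcium pump of the endoplasmic reticulum, was at 2.62 FPKM in the parent and between 17.4 and 26.2 in the 4 lines (log2 2.54, adjusted p = 0.125). CLIC3, a chloride channel protein, was at 6.78 and between 26.5 and 45.2 (2.24), and ALDOC, a glycolytic aldolase, at 3.10 and between 13.1 and 24.2 (2.18). MUCL1, a small mucin of the breast, and SPINK4, a protease inhibitor, were listed at 0 in the parent and at 5.12 or more and 5.91 or more FPKM in the resistant lines. The unnamed loci XLOC_005989 (6.85 to 13.1) and XLOC_018240 (3.08 to 13.9) were likewise listed at 0 in the parent. CXCR7, a scavenging receptor for the chemokine CXCL12, was at 0.783 FPKM and between 4.78 and 16.2 (2.40, adjusted p = 0.386). Among receptors and regulators named in advance, ERBB2, the HER2 receptor, was at 6.88 FPKM in the parent and between 13.1 and 14.9 (log2 0.92, standard error 0.27). BCL2, an inhibitor of apoptosis, was at 21.7 and between 6.02 and 11.1 (−1.38), cyclin D1 (CCND1) at 238 and between 62.3 and 141 (−1.34). FGFR1, a fibroblast growth factor receptor, was at 6.28 and between 4.87 and 8.39 (0.03, and −0.08 without TAMR1 or −0.03 without TAMR8), and EGFR, the epidermal growth factor receptor, below 1 FPKM in every line.

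**Figure D1:**
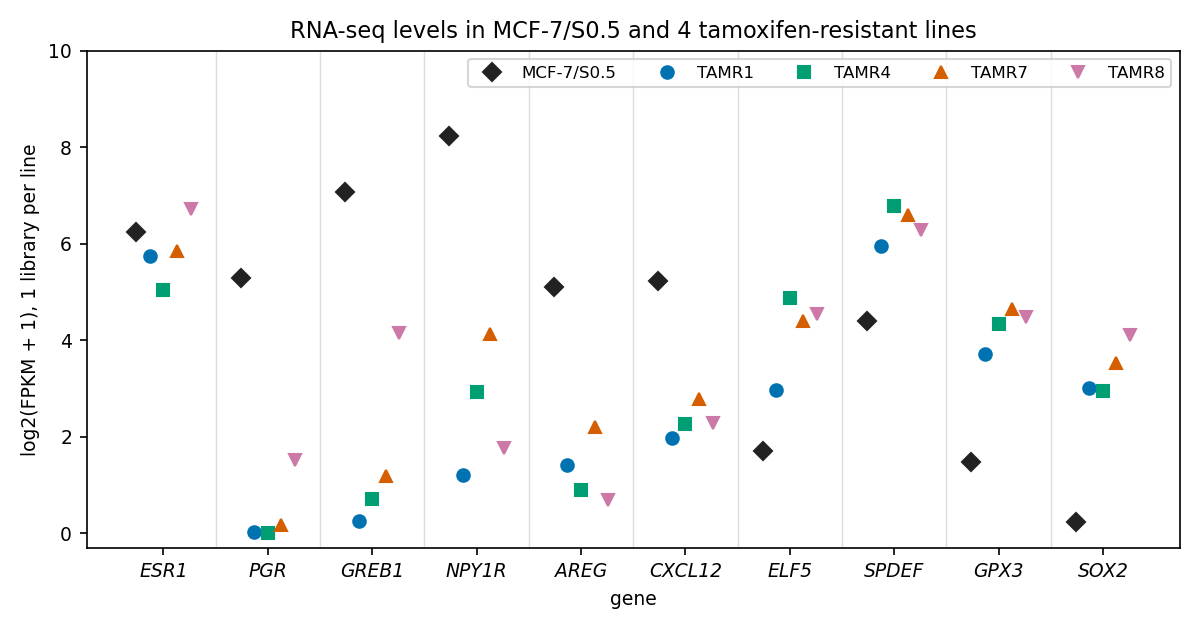
RNA-seq level, as log2 of FPKM plus 1, of 10 genes in MCF-7/S0.5 and the 4 TAMR lines (1 library each, 1 point per line). PGR was at 38.2 FPKM in the parent and at most 1.87 in a TAMR line, and SOX2 at 0.173 and at least 6.75.

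With 4 resistant lines against a single parental library, limma called 2 of 12352 genes, 0 higher and 2 lower, and 883 genes had an unadjusted p under 0.05. The 2 are SCARNA21, a guide RNA of small Cajal bodies, at 15015 FPKM in the parent and listed at 0 in 4 of 4 resistant lines (limma adjusted p = 5.14e-06), and XLOC_003331. The latter was at 269 FPKM and listed at 0 in 4 of 4 lines (limma adjusted p = 2.12e-04). That locus spans 199 bp, and SCARNA21 is a short RNA as well, though its entry spans 27953 bp. For transcripts this short an FPKM of 0 can be an estimate that failed rather than an absence, so neither call establishes a loss. The calls also depended on the pseudocount. At 0.1 XLOC_003331 lost its call, while XLOC_005989 (log2 6.38) and MUCL1 (6.35), both listed at 0 in the parent, gained a call as higher. Leaving out TAMR7 brought the count to 5 by adding IL20 (−4.62), NPY1R (−6.26) and XLOC_002484 (−4.12). Leaving out TAMR8 brought it to 5 by adding ELOVL2 (−5.01), PGR (−5.23) and GREB1 (−6.35).

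As groups fixed before the data were examined, 4 gene lists rose and 3 fell with the preset correlation of camera, and 0 passed with an estimated correlation. All 21 measured genes of cholesterol synthesis were above the parent on average (median log2 1.16, camera adjusted p = 9.31e-10, adjusted p = 0.534 with an estimated correlation, 0 passing when adjusted over the list alone). Among them MVK, mevalonate kinase, was at 0.764 FPKM in the parent and 3.72, 7.41, 11.2 and 2.91 in TAMR1, TAMR4, TAMR7 and TAMR8, and FDFT1, squalene synthase, at 71.9 and 129, 281, 211 and 319. Of 23 estrogen receptor targets 18 were lower and the list fell (median −0.82, camera adjusted p = 1.65e-06, adjusted p = 0.404 with an estimated correlation), and adjusted over the list alone 7 passed. Beyond PGR and GREB1 these targets include AREG, amphiregulin, a ligand of EGFR, at 33.6 FPKM and between 0.612 and 3.63 (−3.81), and CXCL12, at 36.3 and between 2.91 and 5.88 (−2.90). None of the 26 interferon response genes was above the parent on average, and the list fell (median −1.99, camera adjusted p = 8.18e-06, adjusted p = 0.690 with an estimated correlation, 0 passing when adjusted over the list alone). Its spread between lines was wide. IFITM1, an antiviral membrane protein, had 690 FPKM in the parent and 581, 95.3, 58.6 and 1.87 in TAMR1, TAMR4, TAMR7 and TAMR8, and IFIT1, which binds viral RNA, 231 and 251, 36.6, 31.9 and 0.891. Luminal markers rose (14 of 18 above 0, median 0.33, camera adjusted p = 3.31e-04, adjusted p = 0.404 with an estimated correlation, 1 passing when adjusted over the list alone). ELF5, a transcription factor of alveolar cells, was at 2.28 FPKM and 6.83, 28.4, 20.2 and 22.5, and SPDEF, a transcription factor of secretory epithelium, at 20.0 and between 60.7 and 110. Cell cycle genes rose (26 of 28 above 0, median 0.55, camera adjusted p = 0.00231, adjusted p = 0.740 with an estimated correlation, 0 passing when adjusted over the list alone). RRM2, a subunit of ribonucleotide reductase, was at 16.3 FPKM and 53.04, 155, 131 and 25.6, and CCNE2, cyclin E2, at 3.19 and 5.91, 14.3, 12.7 and 4.31. Growth factor receptors and ligands fell (4 of 16 above 0, median −0.80, camera adjusted p = 0.00975, adjusted p = 0.534 with an estimated correlation, 5 passing when adjusted over the list alone). This call was lost without TAMR1 (camera adjusted p = 0.0621) and without a filter (0.0746), in a range from 0.00234 to 0.0746 over the settings. IGF1R, the receptor of insulin-like growth factor 1, was at 26.7 FPKM and 10.02, 0.0126, 0.0551 and 4.24, while IGFBP3, which binds such factors, was at 0.0606 and 1.71, 8.59, 8.11 and 10.5. Drug transport and tamoxifen metabolism rose (8 of 10 above 0, median 0.78, camera adjusted p = 0.0268, adjusted p = 0.534 with an estimated correlation, 0 passing when adjusted over the list alone). It was lost without TAMR8 (camera adjusted p = 0.0506), after median-centring (0.0638) and without a filter (0.373), in a range from 0.00807 to 0.373. Its member CYP1B1, a cytochrome that metabolises estrogens, was at 8.005 FPKM and 12.3, 49.7, 62.2 and 37.2. The members EBP and DHCR7 are enzymes of cholesterol synthesis as well, the latter at 52.8 and between 93.5 and 239.

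The other 12 lists did not pass with camera. The estrogen receptor and its cofactors had a median log2 of −0.13 (6 of 16 above 0, camera adjusted p = 0.688). FOXA1, a pioneer factor of the receptor, was at 55.3 FPKM in the parent and between 73.5 and 139. Cyclin-dependent kinase inhibitors and p53 targets had −0.31 (4 of 16, adjusted p = 0.367), with GDF15, a stress cytokine, at 133 FPKM and 111, 32.8, 40.1 and 24.1. Apoptosis regulators had −0.15 (7 of 18, adjusted p = 0.122), with the pro-apoptotic BCL2L11 at 33.5 FPKM and 22.4, 11.8, 11.5 and 11.7, and passed only with a mean of at least 5 (adjusted p = 0.0320, in a range to 0.290). Basal markers had −0.52 (3 of 7, adjusted p = 0.425), with keratin KRT17 at 17.0 FPKM and 1.75, 7.31, 9.53 and 0.239. Genes of epithelial-mesenchymal transition had −0.29 (3 of 10, adjusted p = 0.688, and 0.0398 without a filter in a range to 0.886), with SERPINE1, a plasminogen activator inhibitor, at 9.37 FPKM and at most 2.17. Unfolded protein response genes had −0.39 (8 of 20, adjusted p = 0.688), with DDIT3, a stress-induced transcription factor, at 91.1 FPKM and 78.5, 7.25, 16.5 and 46.4. Hypoxia and glycolysis genes had 0.27 (13 of 20, adjusted p = 0.221), with VEGFA, a factor of vessel growth, at 80.1 and between 11.7 and 27.8. NF-kappaB and cytokine genes had −0.27 (2 of 10, adjusted p = 0.0628, and 0.0391 without a filter and 0.0491 without TAMR4 in a range to 0.149), with IL6ST, a shared cytokine receptor chain, at 20.5 FPKM and between 3.98 and 9.24. HOX and stem cell genes had 0.15 (8 of 14, adjusted p = 0.966), with SOX9, a developmental transcription factor, at 4.55 FPKM and at most 0.297 next to the high SOX2. DNA methylation and cancer-testis genes had 0.07 (6 of 12, adjusted p = 0.966), with the DNA methyltransferase DNMT3A at 10.7 and between 4.73 and 8.15. Markers of other cell types were barely measured (3 of 27 members, all above 0, median 0.42, adjusted p = 0.122), with the collagen COL1A1 at 0.506 FPKM and between 1.25 and 2.91. Mitochondrial, ribosomal and histone transcripts had −0.27 (4 of 13, adjusted p = 0.966), with RPL13A, a ribosomal protein, at 3839 FPKM and 4713, 1129, 1589 and 3034. Adjusted over the list alone, 3 HOX and stem cell genes, 2 of epithelial-mesenchymal transition, 2 of hypoxia and glycolysis and 0 of each other list in this paragraph passed.

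Taken one at a time, TAMR4 and TAMR7 had higher RRM2 and MVD, an enzyme of the mevalonate pathway (40.0 and 48.6 FPKM against 6.42 in the parent), than TAMR1 (13.4) and TAMR8 (12.9). TAMR8 had little of the interferon gene IFIT1, and TAMR1 was near the parent in it. At least 2-fold, 599 genes were higher and 453 lower in TAMR1, 945 and 1338 in TAMR4, 946 and 948 in TAMR7, and 688 and 1025 in TAMR8, whose median gene was at log2 −0.17. In all 4 lines at once 103 genes were higher and 215 lower, 318 together. Lines that share only the same parental library gave a mean of 37.1 and 42.7 and at most 54 and 56 in 100 simulated draws. The draws treat the 4 lines as otherwise independent, whereas TAMR4 and TAMR7 were nearly alike (411 genes at least 2-fold apart, against 1052 or more in every other pair). Independent draws may therefore understate the count expected in all 4 lines. These are single libraries without a test, and without TAMR1 the shared count was 592 (151 higher and 441 lower).

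Among miRNAs, miR-345-5p, miR-203a and miR-3187-3p were higher in each of the 4 TAMR lines. Against 19.7 CPM in the parent miR-345-5p was at 95.8, 92.8, 138 and 139 in TAMR1, TAMR4, TAMR7 and TAMR8 (log2 2.06, standard error 0.57, edgeR adjusted p = 0.342). A regulator of epithelial differentiation, miR-203a, was at 414 CPM and between 1597 and 2316 (1.81, edgeR adjusted p = 0.482). The rare miR-3187-3p was at 1.09 CPM and between 9.06 and 14.2 (2.89), and miR-152-3p, which targets DNMT1, at 416 and between 1015 and 1717 (1.13). On the other side were miR-95-3p (91.1 CPM in the parent, 16.7 to 44.8 in the lines, log2 −2.12), miR-4504 (10.4, 3.04 to 4.34, −2.03), miR-181c-5p (34.1, 5.45 to 20.0, −1.996) and miR-146b-5p, a repressor of NF-kappaB signaling (168, 36.8 to 102, −1.78). The abundant miR-21-5p, an oncogenic miRNA, was at 124031 CPM and between 77876 and 150488, miR-200c-3p, a guardian of epithelial identity, at 48349 and between 47861 and 76129, and miR-221-3p, which represses ESR1, at 23.4 and between 37.7 and 61.1.

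With edgeR 0 of 583 miRNAs passed and 42 had an unadjusted p under 0.05. DESeq2 called 2, miR-345-5p (log2 2.15, adjusted p = 0.00804) and the rare miR-6857-3p (7.51 CPM in the parent, at most 0.304 in the lines, adjusted p = 0.0210), named after their values were seen. Without TAMR8 edgeR called 1, again miR-6857-3p (adjusted p = 0.0476). None of the miRNA lists passed camera. The 14q32 cluster, miRNAs of the imprinted DLK1-DIO3 region, came nearest with all 5 measured members above 0 (median log2 2.83, camera adjusted p = 0.277). Most of its reads were in TAMR8, where the whole list had 46.3 CPM against 0.820 in the parent and 4.11, 8.82 and 10.3 in TAMR1, TAMR4 and TAMR7. For instance, miR-379-5p was at 11.6 CPM in TAMR8 and at most 0.312 in the parent and the other 3 lines. Medians and camera adjusted p were −0.09 and 0.715 for the miR-200 family, 0.03 and 0.852 for miR-221 and miR-222, −0.32 and 0.727 for let-7, 0.13 and 0.715 for the miR-17-92 clusters. They were −0.27 and 0.783 for the miR-99a, miR-100 and miR-125b clusters. For the rest they were 0.24 and 0.783 for HOX cluster miRNAs, 0.29 and 0.798 for estrogen-linked miRNAs, −0.35 and 0.493 for the miR-15/16 and miR-34 families, 2.22 and 0.493 for the 19q13 cluster (2 members), and −0.41 and 0.727 for miRNAs of other cell types. Adjusted over the list alone, 1 member of the 14q32 list passed and 0 of every other.

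In the LCC model the first step, from estrogen-dependent LCC0 to estrogen-independent LCC1, had inflammatory and interferon genes at far higher levels. CCL2, a chemokine for monocytes, was listed at 0 in LCC0 and at 243 FPKM in LCC1 (DGE 1.68 and 2096 scaled tags). CFB, complement factor B, was at 0.0883 and 191 FPKM, and LTB, lymphotoxin beta, at 0 and 137 FPKM (0 and 1878 tags). TNF, a master cytokine of inflammation, was at 0 and 22.6 FPKM, the neutrophil chemokine IL8 at 0.107 and 21.8, and OAS2, an antiviral enzyme, at 1.12 and 46.0. CD74 and HLA-DRA, which serve antigen presentation by class II molecules, were at 0.672 and 124 and at 0 and 21.3 FPKM. Estrogen-linked genes were on the opposite side, with PDZK1, a scaffold protein, at 169 and 2.99 FPKM (1640 and 8.50 tags), and NPY1R at 395 and 9.55. AREG was at 65.0 and 0.827, EGR3, an immediate early transcription factor, at 47.9 and 2.56, and PGR at 17.5 and 0.634 in LCC0 and LCC1. CHGA, a granule protein of neuroendocrine cells, was at 79.7 and 1.84 FPKM, HPGD, a prostaglandin-degrading enzyme, at 30.5 and 1.23, and MPPED2, a phosphodiesterase, at 18.9 and 1.05. ESR1 itself was higher in LCC1 (58.6 and 108 FPKM, 299 and 710 tags), and GREB1 was at 69.2 and 18.4 FPKM.

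By group, 25 of 26 interferon response genes in RNA-seq and 23 of 27 in DGE were at least 2-fold higher in LCC1 (median log2 2.41 and 2.47), above all 10000 random lists of matched expression. IFI6, a mitochondrial interferon-induced protein, was at 61.0 and 1323 FPKM. Of the NF-kappaB and cytokine genes 12 of 17 in RNA-seq and 14 of 18 in DGE were at least 2-fold higher (median 2.56 and 2.04, above all random lists). Of 24 estrogen receptor targets 10 were at least 2-fold lower in either assay and 0 higher (median −0.51 and −0.85, below all random lists). Apoptosis regulators (median 0.31, percentile 99.7) and the 4 measured basal markers (0.99, percentile 99.7) were above the random lists in RNA-seq alone. Luminal markers (−0.52, percentile 1.68), cholesterol synthesis (−0.49, 1.68), cell cycle (−0.45, 1.67) and mitochondrial, ribosomal and histone transcripts (−0.79, 0.140) were below them in DGE alone, the last at percentile 15.9 in RNA-seq. The remaining lists lay inside the random lists in both assays, among them growth factor receptors and ligands, unfolded protein response, and markers of other cell types (3 members in RNA-seq, median −0.27, percentile 16.6).

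In both assays 400 genes were at least 2-fold higher and 156 lower in LCC1, and 18 had opposite signs, with r = 0.693 across 5749 genes. These counts compare single libraries without a test, and the median gene in DGE was at log2 −0.15. The tests deposited by the authors, also of single libraries, called 131 genes higher and 49 lower in LCC1.

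Tamoxifen-selected LCC2 differed little from LCC1 in RNA-seq and held lower levels of the inflammatory genes. CCL2 was at 243 FPKM in LCC1 and 64.3 in LCC2 (2096 and 446 tags), CFB at 191 and 38.1, CD74 at 124 and 11.97, and HLA-DRA at 21.3 and 1.75. S100A7, psoriasin, an antimicrobial S100 protein, was at 36.4 and 1.21 FPKM, SNCG, gamma-synuclein, at 16.9 and 1.35, and GDF15 at 54.7 and 8.13. STC1, the hormone stanniocalcin, was at 12.3 and 1.04, and CYP4F22, a fatty acid hydroxylase, at 6.96 and 0.663. Higher in LCC2 were IGFBP5, a binding protein of insulin-like growth factors (5.47 and 43.1 FPKM, 31.2 and 228 tags), LCP1, an actin-bundling protein (16.4 and 93.4), and TARP, a T-cell receptor gamma transcript found in prostate and breast cancer cells (81.0 and 343). So were RAB37, a small GTPase (2.93 and 20.6), PADI2, a peptidylarginine deiminase (1.11 and 9.64), CDH18, a cadherin (1.87 and 9.75), HPGD (1.23 and 8.75), and CLEC3A, a C-type lectin (0 and 3.19). ESR1 was at 108 FPKM in LCC1 and 81.4 in LCC2, PGR at 0.634 and 0.144, and BCL2 at 23.03 and 11.001.

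Interferon response genes were below the random lists in both assays (median −0.50 in RNA-seq and −0.66 in DGE, percentiles 0 and 0.360). NF-kappaB and cytokine genes (−0.47, percentile 0), estrogen receptor targets (−0.23, 0.1), HOX and stem cell genes (−0.52, 0), apoptosis regulators (−0.17, 1.04) and unfolded protein response genes (−0.17, 0.720) were below them in RNA-seq alone. The NF-kappaB list was at percentile 2.55 in DGE. The other 13 lists were inside the random lists in both assays, cell cycle genes at a median of 0.10 in RNA-seq. HLA-C, a class I molecule in the interferon list, was at 278330 FPKM in LCC1 and 52737 in LCC2 but at 231 and 144 tags, so its size depends on the assay. At least 2-fold in both assays, 49 genes were higher and 78 lower in LCC2, with 38 opposite and r = 0.130 across 5349 genes. The spread of DGE changes (standard deviation 2.11) was far above that of RNA-seq (0.348). The authors' deposited tests called 11 genes higher and 16 lower in LCC2.

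Fulvestrant-selected LCC9 had little ESR1 and yet high levels of several estrogen receptor targets. ESR1 was at 108 FPKM in LCC1 and 12.7 in LCC9 (710 and 78.9 tags). AREG was at 0.827 and 39.2 FPKM (12.8 and 1116 tags), PGR at 0.634 and 18.1 (1.42 and 185 tags), GREB1 at 18.4 and 76.7, and TFF1 at 4121 and 6977. The median gene of this pair lay at log2 −0.24 in RNA-seq, and changes given with it here are relative to that median. SAA1, an acute-phase protein, was at 1.66 and 212 FPKM (log2 6.57), ASCL1, a transcription factor of neuroendocrine cells, at 1.21 and 173 (6.54), and MUCL1 at 1.42 and 95.9 (5.57). PRSS23, an estrogen-linked serine protease, was at 5.36 and 173 (5.02), PI15, a peptidase inhibitor, at 0.303 and 25.3 (4.58), and MECOM, a zinc finger oncoprotein, at 0.281 and 14.5 (3.84). Lower in LCC9 were TNFRSF11B, osteoprotegerin, a decoy receptor of bone remodeling (82.7 and 2.26 FPKM, log2 −4.44), CCL2 (243 and 11.2, −4.08), and SNCG (16.9 and 0.485, −3.34). Lower too were CACNG4, a calcium channel subunit (64.3 and 4.61, −3.30), GSTP1, a detoxifying glutathione transferase (56.9 and 5.62, −2.88), INHBB, an inhibin subunit (21.8 and 2.67, −2.39), and NOV, a matricellular protein (5.89 and 0.114, −2.38). BCL2 was at 23.03 FPKM in LCC1 and 10.6 in LCC9, and FGFR1 at 4.89 and 10.6.

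List medians of this pair are not relative to the median gene, and the medians of random lists lay between −0.33 and −0.16 in RNA-seq and between 0.08 and 0.21 in DGE. Estrogen receptor targets were above the random lists in both assays (median 0.74 in RNA-seq, 11 of 25 at least 2-fold higher, percentile 100, and 0.98 in DGE, 12 of 24, percentile 100.0). At least 2-fold lower were 4 of them in RNA-seq and 5 in DGE, and KCNK5, a potassium channel, was at 21.9 and 2.80 FPKM. Growth factor receptors and ligands (0.53, percentile 100, and 0.91, percentile 99.8) and hypoxia and glycolysis genes (0.29 and 0.76, percentiles 100.0 and 99.0) were above them too. The receptor KIT was at 0.133 and 5.61 FPKM and IGF1R at 4.31 and 11.5. Cell cycle genes were below in both assays (−0.76 and −0.31, percentiles 0 and 2.46), with CCNB2, a mitotic cyclin, at 55.6 and 19.6 FPKM. NF-kappaB and cytokine genes (−0.65, percentile 0.0200, DGE 3.74), drug transport (−0.58, 0.650) and cholesterol synthesis (−0.54 where its random lists had −0.32, 0.690) were below in RNA-seq alone, and the receptor's cofactors in DGE alone (−0.59, 0.830). Basal markers differed by assay (−0.58 and percentile 2.41 in RNA-seq, 1.12 and 97.7 in DGE). The remaining lists were inside the random lists in both assays, and mitochondrial, ribosomal and histone transcripts stood at percentile 96.6 in RNA-seq.

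**Figure D2:**
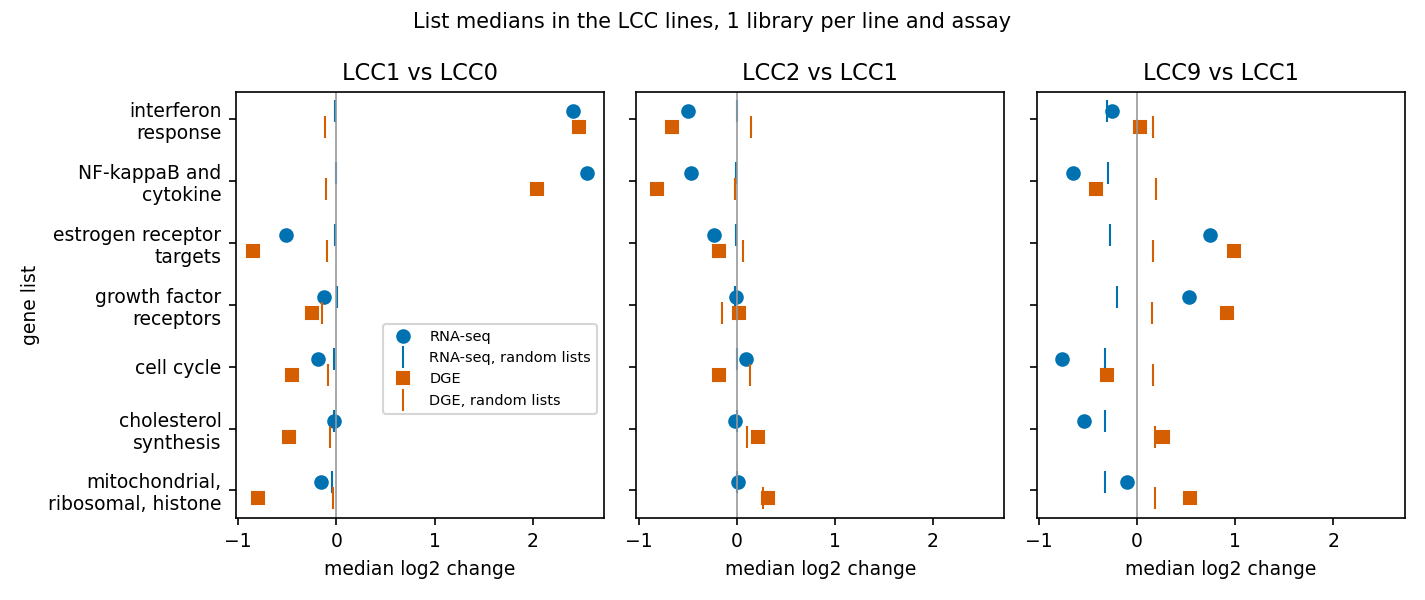
Median log2 change of 7 gene lists in LCC1 against LCC0, LCC2 against LCC1 and LCC9 against LCC1, with RNA-seq as circles, DGE as squares and the median of random lists as vertical ticks. Interferon genes had a median of 2.41 in the first pair and −0.50 in the second, and estrogen receptor targets 0.74 in the third, all in RNA-seq.

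In both assays 170 genes were at least 2-fold higher and 239 lower in LCC9, with 45 opposite and r = 0.379 across 5521 genes, and after median-centring these were 230 and 142. The authors' deposited tests called 57 genes higher and 50 lower in LCC9. LCC2 and LCC9 share LCC1 as their control, so part of what they have in common may come from the LCC1 library.

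The miRNAs of 14q32 traced a path of their own through the LCC lines, with a sum of 1805 CPM in LCC0, 223 in LCC1, 2519 in LCC2 and 3174 in LCC9. All 15 members with enough reads were at least 2-fold lower in LCC1 than in LCC0 (median log2 −2.96). All 14 were higher in LCC2 than in LCC1 (median 3.27), and all 15 were higher in LCC9 than in LCC1 (median 3.87). For instance, miR-379-5p was at 69.4 CPM in LCC1 and 845 in LCC2, miR-381-3p at 93.9, 5.75 and 94.8 in LCC0, LCC1 and LCC2, and miR-134-5p at 16.9, 222.1 and 312 in LCC1, LCC2 and LCC9. Apart from this cluster, miR-184 was at 117 CPM in LCC0 and 772 in LCC1, miR-30a-5p at 123 and 689, miR-21-3p at 5.02 and 31.2, and its partner strand miR-21-5p at 25169 and 79157. On the other side, miR-489-3p was at 159 and 6.02 and miR-653-3p, its neighbor on chromosome 7, at 25.6 and 1.20.

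**Figure D3:**
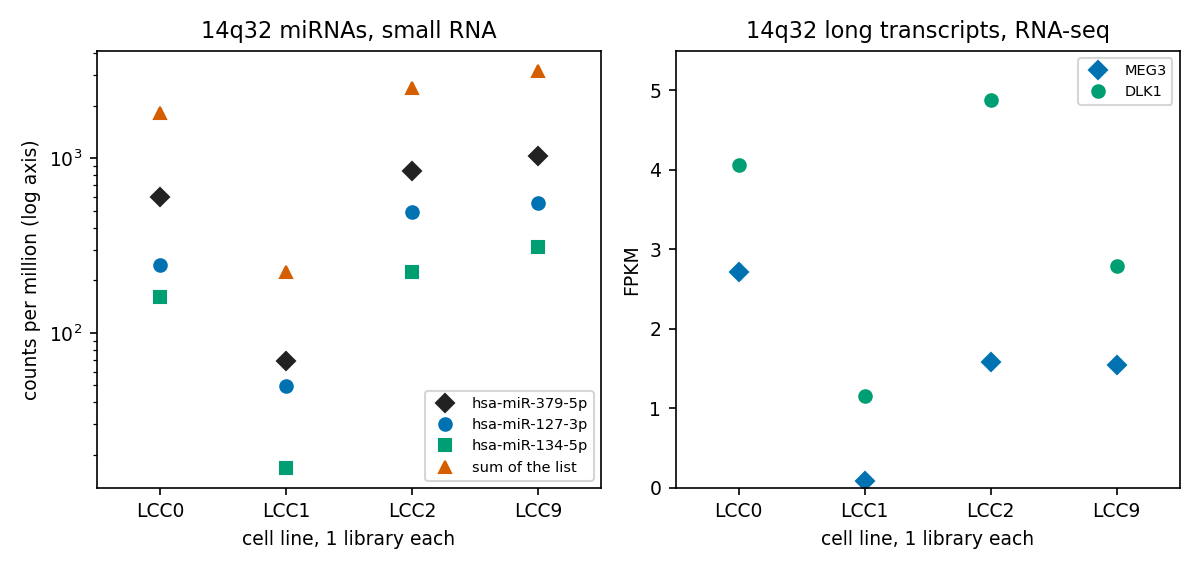
CPM (log axis) of 3 miRNAs of the 14q32 cluster and of the sum of the list, and FPKM of MEG3 and DLK1 from the same region, in the 4 LCC lines (1 library each). The sum was 223 CPM in LCC1 and at least 1805 in the other lines.

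In LCC2 the HOX cluster member miR-196a-5p was lower, at 96478 CPM in LCC1 and 42968 in LCC2, and miR-9-5p was at 537 and 268. In LCC9 miR-10a-5p, a miRNA of the HOXB cluster, was at 34992 CPM (95% Wilson interval 34860 to 35123) against 1422 in LCC1 (1395 to 1449). The genes HOXB3 and HOXB2 of that cluster were at 2.06 and 2.42 FPKM in LCC9, and HOXB3 was listed at 0 and HOXB2 at 0.227 in LCC1. The inflammatory regulator miR-146a-5p was at 17.5 CPM in LCC9 and had no reads in LCC1, which allows up to 0.401 CPM. Lower in LCC9, miR-27b-3p was at 3130 and 1185, miR-184 at 772 and 216 and miR-625-5p at 12.7 and 1.74 in LCC1 and LCC9. At least 2-fold, 55 miRNAs were higher and 37 lower of 265 in LCC1 against LCC0, 31 and 6 of 260 in LCC2 against LCC1, and 52 and 11 of 279 in LCC9 against LCC1. With TMM scaling these were 43 and 42, 25 and 8, and 44 and 18, so the excess of higher miRNAs in LCC1 against LCC0 depended on the scaling. Over the 3 pairs in this order the list medians were 0.31, −0.18 and −0.33 for the miR-200 family, −0.08, 0.28 and 0.07 for let-7, −0.73, 0.13 and 0.69 for the miR-17-92 clusters. They were −0.02, −0.02 and −0.18 for the miR-99a, miR-100 and miR-125b clusters, and −0.39, −0.62 and −0.01 for HOX cluster miRNAs. The medians were 0.63, −0.16 and 0.13 for estrogen-linked miRNAs, 0.11, 0.02 and −0.20 for the miR-15/16 and miR-34 families, and 0.99, −0.33 and 0.21 for miRNAs of other cell types, and no member of the miR-221 list or of 19q13 had enough reads.

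Between the tamoxifen-resistant lines LCC2 and LCC9 and the sensitive lines LCC0 and LCC1, the genes farthest apart in both assays included several for which both lines of a group lay on the same side of the other 2. CRABP1, a retinoic acid binding protein, was at 15.6, 8.19, 1.83 and 0.898 FPKM in LCC0, LCC1, LCC2 and LCC9 (log2 −2.42, standard error 0.39, limma adjusted p = 0.992). CYP4F22 was at 6.67, 6.96, 0.663 and 1.02 (−2.09), and CNN2, an actin-binding calponin, at 19.7, 6.19, 2.42 and 1.74 (−1.995). SLC5A8, a monocarboxylate transporter, was at 0.907, 3.98, 8.93 and 22.6 FPKM (log2 2.31, standard error 0.60), and TARP at 31.2, 81.0, 343 and 175 (2.26). CGA, the alpha subunit of glycoprotein hormones, was at 0, 6.47, 11.97 and 52.1 (3.26), and PYDC1, a regulator of the inflammasome, at 0, 7.96, 11.9 and 17.0 (2.35). For others the mean hid a single line, as for SAA1 and ASCL1 (high in LCC9), CHGA, NPY1R, PDZK1 and RHOBTB3 (high in LCC0, the last a Rho-related protein at 116, 17.0, 11.8 and 9.90 FPKM), LTB and CFB (near 0 in LCC0), and CACNG4 (low in LCC9). Without LCC0 the mean change was −0.98 for LTB, −1.51 for CFB, 0.13 for NPY1R and 0.27 for PDZK1.

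With 2 libraries in each group, limma called 0 of 12513 genes in RNA-seq, where 254 had an unadjusted p under 0.05 and the median gene was at log2 −0.11. Without LCC0 the count was 12 and without LCC1 34, while without LCC2 limma called the nucleolar RNAs SNORA11B and SNORA68 and without LCC9 the small nuclear RNA RNU4ATAC. These 3, named after their values were seen, were listed at 0 in every LCC line except LCC9 or LCC2. In DGE limma called 167 of 13497 genes, 0 higher and 167 lower, with 2133 at an unadjusted p under 0.05, and after median-centring 97 higher and 666 lower. Of these 167, 159 were in RNA-seq, where 125 were lower, with a median log2 of −0.225 against −4.698 in DGE. At least 2-fold lower in RNA-seq as well were 2 of them, EEF1A2 and TMSB4X, named after their values were seen. EEF1A2 is a translation elongation factor (304, 265, 205 and 81.0 FPKM in LCC0, LCC1, LCC2 and LCC9, 894, 334, 5.07 and 4.55 tags), and TMSB4X an actin-sequestering thymosin (1341, 1168, 731 and 272 FPKM, 4010, 2939, 77.5 and 287 tags). The 167 also became 0 with a pseudocount of 0.1 or without any single line, and 331 with edgeR on recovered reads and 956 with DESeq2. None of the 19 gene lists held a gene that passed in RNA-seq, also when adjusted over the list alone (0 for each), with medians between −0.43 for cell cycle genes and 0.66 for interferon response genes.

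Among miRNAs of this comparison let-7b-5p, a tumor-suppressive member of let-7, was at 99809, 109879, 57457 and 56533 CPM in LCC0, LCC1, LCC2 and LCC9 (log2 −1.09, standard error 0.26, edgeR adjusted p = 0.978). On the other side miR-483-5p, which lies within IGF2, was at 10.2, 8.56, 30.9 and 63.0 CPM (2.12). The levels of miR-20b-5p and miR-363-3p, from a shared cluster on the X chromosome, were 6.12, 18.5, 23.9 and 119 and 7.32, 37.2, 36.7 and 176. The highest mean change, log2 3.28 for miR-10a-5p, rested on LCC9 alone (−1.02 without it), and miR-1269a was at 0.328, 12.8, 33.1 and 43.9 CPM. The lowest, miR-653-3p, miR-4760-5p and miR-489-3p, were high in LCC0 alone and turned to 1.20, 1.88 and 1.93 without it. Of 526 miRNAs edgeR called 0, with 13 at an unadjusted p under 0.05 and 0 with DESeq2, and without LCC2 it called 2, miR-10a-5p (log2 4.19, adjusted p = 0.0185) and miR-146a-5p (adjusted p = 0.0256), named after their values were seen. No miRNA list held a member that passed, also when adjusted over the list alone (0 for each), and the 37 tested members of 14q32 had a median of 1.27.

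Over both models together the miRNAs farthest apart in the 6 resistant against the 3 sensitive lines were mostly rare. Lowest at 0.683 CPM in MCF-7/S0.5, 0.983 in LCC0 and 2.01 in LCC1, miR-940 was between 3.08 and 27.3 in the 6 resistant lines (log2 2.46, standard error 0.79, edgeR adjusted p = 0.616). In the same comparison miR-20b-5p was at 3.55 CPM in MCF-7/S0.5 and between 9.98 and 17.9 in the TAMR lines (2.03 over both models, edgeR adjusted p = 0.578). The change of miR-95-3p was −1.13, of miR-424-5p, a regulator of the cell cycle, −1.05, of miR-34c-5p, a p53 target, −1.43, and of miR-196a-5p −1.24. These 4 were lower in every TAMR line than in MCF-7/S0.5, but in the LCC lines the groups overlapped or, for miR-196a-5p, nearly met. In LCC0, LCC1, LCC2 and LCC9 miR-95-3p was at 138, 196, 170 and 132 CPM, miR-424-5p at 167, 95.4, 77.7 and 108, and miR-34c-5p at 16.5, 8.43, 3.74 and 16.5. In the same lines miR-196a-5p was at 130233, 96478, 42968 and 95861 CPM, near its LCC1 level in LCC9. The lowest fitted change, −2.26 for miR-598-3p, came from the LCC lines (2.18, 7.49, 0.258 and 0.134 CPM), since in the TAMR model it was at 42.9 CPM in the parent and between 88.6 and 162 in the resistant lines. Of 608 miRNAs edgeR called 0, with 39 at an unadjusted p under 0.05. DESeq2 called 3, miR-1273g-3p (2.27), miR-3187-3p (1.92) and miR-331-3p (listed at 0 in MCF-7/S0.5 and LCC0, at most 3.74 CPM elsewhere), each at an adjusted p = 0.0223 and named after their values were seen. No list held a member that passed, also when adjusted over the list alone (0 for each), and the 14q32 list had a median of 1.42.

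In RNA-seq, the only mRNA assay of both models, the 2 models shared few gene changes. ELF5 and MUCL1 were at least 2-fold higher in all 4 TAMR lines against their parent and in both LCC2 and LCC9 against LCC1. In LCC1, LCC2 and LCC9 ELF5 was at 3.39, 11.7 and 9.03 FPKM and MUCL1 at 1.42, 16.8 and 95.9, though LCC0 had 13.2 and 22.9. DGE listed ELF5 at 0 tags in LCC1 and also in LCC0, despite its FPKM there. Lower in both were ERRFI1, a feedback inhibitor of EGFR (93.4 FPKM in MCF-7/S0.5 and between 6.65 and 20.5 in the TAMR lines, 10.98, 4.44 and 3.53 in LCC1, LCC2 and LCC9), and RASGRP1, an activator of Ras (20.9 and between 0.927 and 9.49, then 4.40, 0.231 and 0.441). Tamoxifen-sensitive LCC0 had 8.62 FPKM of ERRFI1 and 0.724 of RASGRP1. For RASGRP1 it was thus LCC1 that stood apart from the other LCC lines. These 4 genes are all that met the rule fixed for the overlap, which used RNA-seq alone and not DGE. There were 2 higher where 0.199 were expected and 2 lower where 0.490 were expected among 10705 genes (Fisher's exact p = 0.0168 and 0.0860, as descriptions, because genes are not independent). AMIGO2, an adhesion molecule, and ATXN1, a transcriptional regulator, were lower in TAMR and higher in LCC lines (0.270 expected, Fisher's exact p = 0.0295), and 0 genes were higher in TAMR and lower in LCC lines (0.362 expected).

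Against LCC0 in place of LCC1, 7 genes were higher in both models (1.28 expected, Fisher's exact p = 2.88e-04) and 12 lower (1.09 expected, Fisher's exact p = 7.43e-10). In opposite directions, 7 were lower in TAMR and higher in LCC lines (1.74 expected, Fisher's exact p = 0.00177) and 0 the reverse (0.804 expected). The higher ones were ATP2A3, SPINK4, IGFBP3, UPK2, RHOV, SH3BGRL and HIST1H1C. The lower ones included NPY1R and its sister receptor NPY5R, PDZK1, SUSD3, an estrogen-regulated membrane protein (24.8 FPKM in LCC0 and 2.95, 3.94 and 10.8 in LCC1, LCC2 and LCC9), and DLC1, a Rho GTPase-activating protein. All 12 lower genes were already at least 2-fold lower in tamoxifen-sensitive LCC1 than in LCC0, such as NPY1R (395 and 9.55 FPKM in LCC0 and LCC1). The 7 higher ones were also higher in LCC1, some by less than 2-fold (ATP2A3 15.8 and 53.7, SPINK4 2.19 and 2.82). The overlap against LCC0 thus includes the step from LCC0 to LCC1 and is not particular to tamoxifen resistance. At 1.5-fold 14 genes were shared higher and 17 lower (2.49 and 6.81 expected), while 11 were higher in TAMR and lower in LCC lines (6.17 expected) and 6 the reverse (2.75 expected). Without TAMR1 the 4 shared genes became 13 (3 higher and 10 lower) and without TAMR7 6. All 6 of these lines are compared with only 1 parent each, so a shared parent adds to any overlap within a model but not between them.

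Mean DNA methylation was similar in all lines, with means of 27.6, 28.3, 28.4 and 27.5% in LCC0, LCC1, LCC2 and LCC9, and differed at single regions. Medians were 1.47, 2.63, 2.53 and 1.25%, and means over mitochondrial positions 0.536, 0.989, 0.921 and 0.633%. Both were higher in LCC1 and LCC2, and whether such a low background enters the counts of small differences was not tested. At ABCC13, a transporter pseudogene, a window on chromosome 21 (15646000 to 15646999, 6 CpG pairs) was at 77.6, 0, 50.7 and 45.4% in LCC0, LCC1, LCC2 and LCC9. A window at AES, a Groucho-type corepressor, on chromosome 19 was at 54.6, 2.89, 76.1 and 67.7%. Windows at ARX, a homeobox gene (77.7, 10.1, 24.0 and 12.2%), ATP10A, a phospholipid flippase (70.5, 5.15, 12.9 and 6.49%), and SPRY1, an inhibitor of growth factor signaling (66.8, 9.99, 5.66 and 7.26%), were low in all lines after LCC0. A window at PANX2, a channel protein, was at 73.7, 8.78, 10.4 and 43.0%. Higher after LCC0 was a window at FGF13, an intracellular fibroblast growth factor homolog (30, 83.0, 58.8 and 65.4%), and higher until LCC9 a window at SLC24A3, an ion exchanger (6.79, 58.4, 55.6 and 10.98%).

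Both lines selected with an antiestrogen had high methylation at IRS1, the main substrate of the insulin and IGF1 receptors. A window there on chromosome 2 (227662000 to 227662999, 20 CpG pairs) was at 5.25, 17.0, 76.1 and 76.1% in LCC0, LCC1, LCC2 and LCC9 (standard deviation over CpGs 31.5 in LCC2 and 13.5 in LCC1). A window at KALRN, a Rho exchange factor, was at 68.5, 19.1, 62.4 and 72.8%. A window in the HOXC cluster beside MIR196A2, which is not the only gene of miR-196a, was at 4.78, 6.27, 51.7 and 27.5%. Apart in LCC9 alone were a window on chromosome 6 between 29855000 and 29855999 (13.02, 7.89, 16.5 and 68.3%) and a window beside IRX5, a homeobox gene (29.0, 4.19, 17.6 and 59.4%). The window on chromosome 6 is listed with HCG4, HCG4B, HCG9 and a merged entry of HLA-A, HLA-F and HLA-G. It was therefore not tied to a single gene. On the low side were windows at TSHZ3, a zinc finger gene (61.8, 63.7, 45.5 and 8.22%), and at C7orf72 (69.2, 70.1, 57.3 and 3.89%). A window at SDK1, an adhesion molecule, was at 54.3, 69.9, 27.9 and 19.03%.

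**Figure D4:**
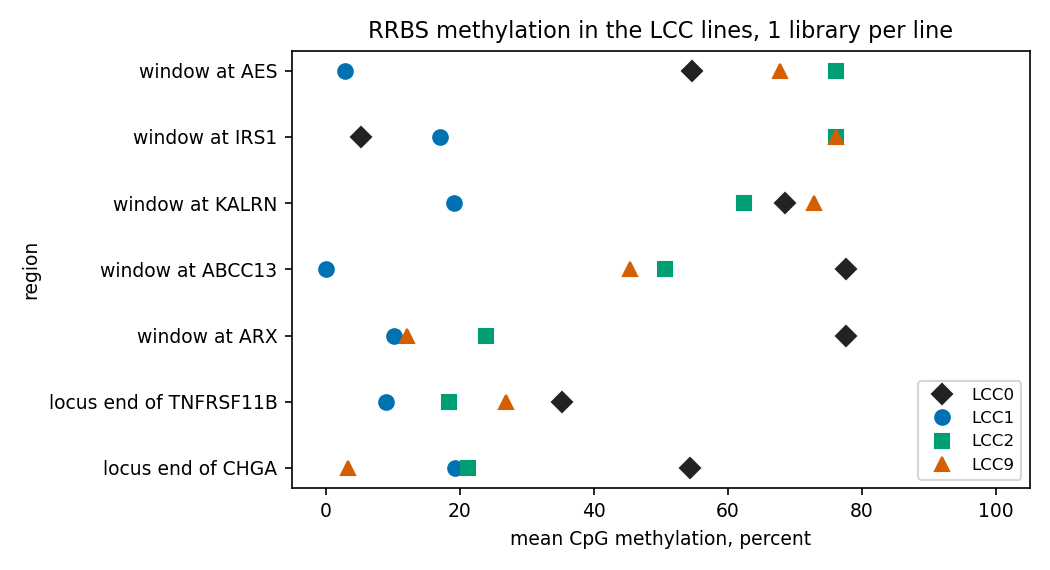
Mean methylation in percent of windows of 1000 bp at AES, IRS1, KALRN, ABCC13 and ARX and of the CpG-rich locus ends of TNFRSF11B and CHGA in the 4 LCC lines (1 library each). The IRS1 window was at 17.0% in LCC1 and 76.1% in LCC2.

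Of 1196043 CpG pairs, 6309 were at least 25 points higher and 7296 lower on both strands in LCC1 against LCC0, where 422 had strands in opposite directions. In LCC2 against LCC1 these were 3015, 3474 and 666, and in LCC9 against LCC1 4838, 6644 and 2041. At a difference of at least 10 points the counts were 34232 higher and 27032 lower in the first pair, 22496 and 22260 in the second, and 22083 and 32305 in the third, so the balance turned in the first and second pair. As windows, 167 were higher and 143 lower of 63715 in the first pair, 53 and 60 in the second, and 110 and 261 in the third. The table has no coverage and each line a single library, so no CpG had a test. Whether the pairs are CpGs was not checked against the sequence. The counts of opposite strands are lowered by the filter on strand gaps and do not measure variation between cultures of a line.

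At TNFRSF11B methylation and expression lay in opposite directions, with 35.2, 8.97, 18.3 and 26.9% at its CpG-rich end in LCC0, LCC1, LCC2 and LCC9 and an FPKM of 0.808 in LCC0, 82.7 in LCC1, 19.1 in LCC2 and 2.26 in LCC9. PRAME, a cancer-testis antigen, was at 39.8 and 11.004% and at 0.361 and 7.40 FPKM in LCC0 and LCC1. PPP1R3C, a glycogen-targeting phosphatase subunit, was at 67.0 and 36.0% and at 0 and 6.31 FPKM, and FAR2, a fatty acyl reductase, at 50.2 and 12.1% and at 1.31 and 8.09 FPKM. SLC16A14, a transporter, had 1.94 and 31.4% and 6.98 and 1.89 FPKM, whereas CHGA had both lower methylation (54.3 and 19.2%) and lower expression. At the ends of ERBB2, CCND1, BCL2 and FGFR1 methylation was below 3% in every line. GSTP1 had 17.8, 22.8, 26.4 and 34.3% in LCC0, LCC1, LCC2 and LCC9.

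Over all genes the change in methylation at the locus end and the change in expression were weakly opposed, with Spearman rho = −0.0791 for LCC1 against LCC0 (9459 genes). It was −0.0459 for LCC2 against LCC1 (9397) and −0.0405 for LCC9 against LCC1 (9522). Among genes whose methylation differed by at least 10 points, only 102, 44 and 72 in the 3 pairs, rho was −0.388, −0.218 and −0.227, and with DGE over all genes −0.0476, −0.0109 and −0.0162. At least 25 points apart were 3 higher and 10 lower ends in LCC1 against LCC0. Of these 6 had lower methylation with at least 2-fold higher expression in RNA-seq, HIST1H4D and PANX2 beside those named above, and 1 (SLC16A14) the reverse, chosen after their values were seen. DGE listed HIST1H4D at 0 tags in both lines and FAR2 at 0 in LCC0 and 1.42 in LCC1, which is near the floor. The rest of the 6 were higher in LCC1 in DGE too. HIST1H4D and PRAME rested on 5 and 6 CpG pairs. In LCC2 against LCC1 2 ends were higher and 0 lower, and in LCC9 against LCC1 2 and 1, none with a 2-fold difference in expression.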

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

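The 3 tests of the 14q32 miRNAs and the comparison of DGE with RNA-seq changes were chosen after the result was seen, and the others before.

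Among the 4 TAMR lines a line stood apart from the other 3 in 8 of 110 checks with Dixon's outlier ratio, where chance gives about 1 in 20. The checks covered named genes, named miRNAs and totals per line, and all 8 were genes. TAMR1 was apart at XLOC_005989 (13.1 FPKM), IGFBP3 (1.71) and BCL2L11 (22.4), TAMR7 at XLOC_002484 (0.710), and TAMR8 at PGR (1.87), BMPER (0.0745), ELOVL2 (2.30) and SOD2 (15.5). For BMPER and XLOC_002484 the other 3 lines were listed at 0, and BMPER in TAMR8 was itself near 0. AMIGO2 and ATXN1 were lower in every TAMR line and higher in LCC2 and LCC9, with the mean log2 change in the TAMR lines below that in the LCC lines (−3.61 and −3.83), a difference that was not tested.

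The 14q32 miRNAs were lower in LCC1 than in LCC0 and in both lines derived from LCC1. A mislabelled small RNA library is argued against by the RNA-seq library of LCC1, where MEG3, the noncoding RNA of the same region, was at 0.0820 FPKM against 2.71, 1.58 and 1.55 in LCC0, LCC2 and LCC9 (log2 −1.24 against the lowest of these). Cells of the TAMR family in the LCC1 culture are argued against by miR-196a-5p, which was at 74.1% of its LCC0 level where the 14q32 sum was at 12.3%. Higher methylation of the covered CpGs is argued against by the 1 of 1162 CpG pairs (0.0861%) between DLK1 and DIO3 that was at least 25 points higher in LCC1 than in LCC2. That holds only if these pairs are CpGs, which was not checked. A candidate explanation that stays open and was not tested is that the LCC1 stock measured here lost expression of the region after LCC2 and LCC9 had branched off.

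DGE changes of LCC2 against LCC1 had a spread far above those of RNA-seq. Depth is argued against, because after thinning all tag libraries to 1337910 reads the ratio of the spread to that of LCC1 against LCC0 was 2.09, and 2.05 before. A change in transcripts that RNA-seq also measures is argued against, because of 1174 genes 4-fold apart in DGE 30 (2.56%) were 2-fold apart the same way in RNA-seq. A difference in library preparation shared by LCC2 and LCC9 may be part of it, because LCC2 against LCC0 and LCC9 against LCC1 correlated with r = 0.658 in DGE and r = −0.196 in RNA-seq across 5566 genes. Since LCC2 and LCC9 are also the resistant lines, any biological share of these DGE changes stays open and untested.

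Neighboring genes differed from the parent line in the same direction. Over 7 comparisons 3965 blocks of 31 genes had a median of at least 0.4 (log2) in either direction where the highest of 100 shuffled orders had 168. Blocks, here and above, are runs of neighboring genes moved along gene by gene, so they overlap and are not separate regions. Their number ran from 62 in LCC2 against LCC1 to 1394 in TAMR4. The TAMR comparisons share the MCF-7/S0.5 library, and those of LCC2 and LCC9 share LCC1. Reads shared by overlapping loci are argued against by 3406 blocks without such loci (highest shuffled 159), and a trend with gene density by 2639 blocks after regressing it out (highest shuffled 153). A regional difference between the lines, such as DNA copy number, is a candidate explanation, because RNA-seq and DGE block medians of LCC1 against LCC0 correlated with r = 0.805 over 178 blocks that share no gene (highest shuffled 0.518, r = 0.702 over genes). The series holds no DNA copy number data that would separate it from other regional causes.

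In the comparison of 6 resistant with 3 sensitive small RNA libraries edgeR called 0 miRNAs, with 39 at an unadjusted p under 0.05 and 3 with DESeq2, so chance cannot be excluded. Every one of the 84 splits of the 9 libraries gives at least 0, so the splits add no evidence. The highest other split, with LCC0, LCC1 and LCC2 as the group of 3, gave 3.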

How the results depend on the processing

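Alternatives chosen after the data were seen were median-centring and the limma and edgeR TMM settings for DGE, median-centring and leaving out lines for the single-line counts, summing entries of a symbol, the strand-gap filters, and the list tests under each setting. Counted once per alternative, the main counts and values stayed within the margin set for them in 66 cases and moved in 61. Counted in the same way, named genes and miRNAs kept direction and side of the threshold in 758 cases. They passed it only in the alternative in 23 cases, no longer passed in 1 (XLOC_003331 with a pseudocount of 0.1) and reversed in 12 (FGFR1 in 2 of these). Single gene lists are not in these numbers. Growth factor receptors and ligands lost their call without TAMR1 and without a filter, and drug transport and tamoxifen metabolism without TAMR8, without a filter and when median-centred. NF-kappaB and cytokine genes passed only without a filter or without TAMR4, epithelial-mesenchymal transition only without a filter, and apoptosis regulators only with a mean of at least 5. The cause was not tested, except where fewer lines or genes by construction change a count. RNA-seq and RRBS depth are unknown, and for rare miRNAs and tags counting error limits the values. Alternatives by CpG coverage and by the most abundant transcript were not run, because the files give neither. No paired analysis was possible because each line has 1 library per assay and line numbers do not pair resistant with sensitive lines. Where a line was left out and a group had 1 library, it was assumed to vary like the others.

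Without a filter the number of calls was 58 in TAMR RNA-seq, 7 in TAMR miRNA, 6 in LCC miRNA and 10 over both models' miRNAs. DESeq2 called 2 TAMR miRNAs and 3 over both models. The 167 calls of LCC DGE became 763 when median-centred, 0 with a pseudocount of 0.1, 345 with a mean of at least 5, 331 with edgeR and TMM on recovered reads, 956 with DESeq2, 289 with edgeR and DESeq2 size factors, 0 with library size alone and 1311 without a filter. Leaving out each line gave from 2 to 5 calls in TAMR RNA-seq, from 1 to 34 in LCC RNA-seq, from 0 to 0 in LCC DGE, from 0 to 1 in TAMR miRNA and from 0 to 2 in LCC miRNA.

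Genes 2-fold apart in all TAMR lines numbered 85 at 3-fold and 550 with a pseudocount of 0.1, and from 350 to 592 without each line. In LCC1 against LCC0, LCC2 against LCC1 and LCC9 against LCC1 genes apart in both assays numbered 219, 30 and 130 at 3-fold, 878, 269 and 770 in RNA-seq alone, and 5340, 6860 and 6508 in DGE alone. With a pseudocount of 0.1 the second and last were 247 and 627, and with a level of at least 5 the second was 83. With at least 100 CPM 37, 14 and 22 miRNAs were apart. Genes shared between models in the same direction numbered 31 at 1.5-fold, 19 against LCC0 and from 4 to 13 without each line.

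CpG pairs at least 10 points apart numbered 61264, 44756 and 54388 in the 3 pairs, and with a strand gap of at most 10 points 6867, 3062 and 5443. For methylation against expression rho was −0.0476, −0.0109 and −0.0162 with DGE, −0.388, −0.218 and −0.227 for changes of at least 10 points, and −0.0592 and −0.0273 in the first and last pair within 500 bp.

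Reversed without a line were TFF1 (−0.89 to 0.29) and FGFR1 (−0.082 to 0.14) in the TAMR model, and in the LCC model LTB (−0.98 to 6.13), CFB (−1.51 to 5.96), NPY1R (−5.10 to 0.13), PDZK1 (−5.14 to 0.27), miR-10a-5p (−1.02 to 4.19), miR-653-3p (−3.36 to 1.20), miR-4760-5p (−3.97 to 1.88) and miR-489-3p (−2.95 to 1.93). Over both models miR-598-3p reversed to 1.85 without a model term.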

Other observations

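TAMR4 and TAMR7, isolated as separate lines, were nearly alike. They had 411 genes at least 2-fold apart where every other pair of lines in the model had between 1052 and 2283, and 10 of 132 miRNAs apart where the other pairs had between 20 and 44. Both had a low IGF1R (0.0126 and 0.0551 FPKM against 10.0175 in TAMR1), a high RRM2 (155 and 131 against 25.6 in TAMR8) and a high MVD, an enzyme of the mevalonate pathway (40.0 and 48.6 against 12.9). The tests deposited by the authors called 5 genes between TAMR4 and TAMR7 and between 59 and 133 in each other pair.

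Neighboring genes on parts of several chromosomes differed in expression between the lines. Ranges given below are the outermost limits of all such blocks on a chromosome, which need not form a continuous segment. Genes in blocks on chromosome 17 were higher in TAMR4 and TAMR7 (block medians up to log2 1.08 and 0.94) and, less so, in TAMR8 (0.48), all against the same parental library. Genes on the long arm of chromosome 11 were higher in TAMR4 and TAMR7 (0.95 and 0.78). In TAMR8 blocks on 6p between 24667263 and 27560634, a range that holds histone genes, had a median of up to 1.74. Blocks on chromosome 18 were lower in all 4 TAMR lines (down to −0.65, −0.70, −0.67 and −0.55 in TAMR1, TAMR4, TAMR7 and TAMR8), but all 4 are compared with the same parental library, so a feature of that library alone could give this. In LCC1 against LCC0, blocks on the long arm of chromosome 1 between 150190717 and 240072717 were higher (up to 0.61), as were blocks at the end of chromosome 8 (0.77). Blocks on chromosome 14 were lower (down to −0.55).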
